A study of Mus musculus with 22 samples.

How the data were processed

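Spleen RNA of 22 mice was measured on two-colour expression arrays, 1 mouse per array. Per the labels, the spleen RNA of every array was labelled with Cy3 and a universal reference RNA with Cy5, the same way round on all arrays. The mice were SJL/J mice, an inbred strain prone to lymphoma, at 6 weeks (4 mice), 6 months (4 mice) and 12 months (4 mice) of age, and 10 mice of NFS.V+ (called NFSV here), sublines of NFS/N mice that served as the normal control. The labels give no age for the NFSV mice. They call all arrays of a group biological replicates.

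The data were the authors' deposited value table of 37558 numbered rows for all 22 arrays. Each row is called a probe here. The row numbers alone do not show whether some rows repeat a probe or are control spots. Any such rows were tested and counted singly. Per the labels the values come from 2 channels, and the deposited values are signed log ratios of those channels, from -3.09 to 2.85. The deposited values were treated as log10 ratios only where a fold is quoted, always beside the fold that base 2 would give, because the log base is not given in the sources used here. The background correction, the normalization within arrays and the software are not given there either. Nor is it stated whether a ratio is spleen over reference or reference over spleen. The array medians were 0 on 18 arrays, and 0.0176, 0.003985, 0.004105 and 0.005265 on SJL 6 month replicates 1 and 2, SJL 12 month replicate 1 and NFSV replicate 3. Because 7.48% to 25.3% of the rows of an array were at exactly 0, these medians do not show whether the ratios were centred. Over the probes with a value on all arrays the deposited medians were 0.027 to 0.141, and whether and how the authors centred the arrays stays unknown, as do the log base and the direction. Any 2 arrays correlated at 0.714 or more over the probes with a value on all arrays, so all arrays ran the same way.

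The table numbers its rows and pairs no row with a gene, and the gene table at hand does not use these numbers. The tests therefore ran on single probes, in deposited units, where genes on a log2 scale had been planned before the data were examined. The 28 gene lists fixed at that stage (T follicular helper cells, germinal centre B cells, plasma cells, interferon response, pancreas and others), their set tests, the averaging of probes per gene and the panel of named genes were not run. The planned rule for named genes was the largest changes among those past an adjusted p of 0.05 with no overlap between the groups. It was applied to probes for the comparison of SJL mice at 12 months with 6 weeks, and limited to the 2 largest rises and the 2 largest falls.

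A value of exactly 0 was read as a failed estimate and set to missing. This choice was made after the table had been seen. Keeping these values as 0 is one of the alternatives. Each array was then centred on the median of the 25557 probes with a value on all 22 arrays, where the median of the whole array had been planned. Probes needed a value on at least 3 arrays of each SJL group and on 7 NFSV arrays, which left 28371 tested probes. No intensities were used here, so no filter on dim spots could be set, and the precision of each value is limited by the number of arrays.

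Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test), in 1 fit of all 22 arrays with 4 group means and no covariate. In all 6 comparisons were made, 3 between the SJL ages and 3 of an SJL age against NFSV. P-values were adjusted by Benjamini-Hochberg over the tested probes of each comparison, with a threshold of 0.05. The size of the differences over all probes was summarised as the root mean square difference after subtraction of the error variance measured within each of the 2 groups. This estimate, and the simulations of comparisons with shared arrays, first used the variance pooled over the 4 groups. Both were changed to the variance of each group after the pooled values had been seen, because the spread differed between groups (median SD over probes 0.042 in SJL mice at 6 weeks, 0.057 at 6 months, 0.086 at 12 months and 0.095 in NFSV mice). The pooled values are given beside the others. The distance of an array from its group was the root mean square difference from the mean of the other arrays of the group over the 25557 probes, scaled for the number of arrays in that mean, and was compared between groups by an exact two-sided permutation test. The size estimates, the distances and the tests on the share of zeros were chosen after the data had been seen. The fit was tested on simulated data of 28371 probes, with 200 probes changed by known amounts. In the simulated comparison of SJL 12 months with 6 weeks, 58% of changes of 0.3 and 14% of changes of 0.15 were recovered, with 7 false calls. The noise of this test kept the variance pooled over the 4 groups. In 20 simulated data sets without effects that used the variance of each group, this comparison gave 9.25 calls on average and at most 17.

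Comparisons that share the 6 week arrays were set beside 20 simulated data sets without effects, and repeated with 2 of the 6 week arrays in each comparison. Alternatives were no centring, quantile and scale normalization, other limits on missing values, robust and trended variances, array weights, fits of only the 2 groups compared, stricter thresholds, leaving out each array and the replicate number as a block.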

Results

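Gene expression was profiled in the spleens of lymphoma-prone SJL mice at 3 ages, and of NFSV mice as normal controls, to find the patterns that go with age in the SJL strain. There were 4 SJL mice at 6 weeks, 4 at 6 months, 4 at 12 months and 10 NFSV mice, each hybridised once against the same kind of reference RNA. Each value is a deposited log ratio of the 2 channels after centring, given in deposited units because the log base is not stated. Probes are named by their row number, since the table pairs no row with a gene.

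The labels do not settle whether a ratio is spleen over reference or the reverse. Higher and lower below therefore refer to the deposited ratio, and neither is read as more or less RNA in the spleen.

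The number of measured probes differed between the strains. The share of rows at exactly 0 was 11.3% ± 1.35 (SD, n = 4) in SJL mice at 6 weeks, 8.59% ± 1.00 (n = 4) at 6 months and 10.5% ± 1.13 (n = 4) at 12 months, against 21.2% ± 2.56 (n = 10) in NFSV mice. No SJL array reached the lowest NFSV array, which had 18.4% of its rows at 0. Each SJL age differed from NFSV in this share (exact two-sided permutation test over 1001 assignments, p = 0.000999 for each, the smallest the test can give; Benjamini-Hochberg adjusted over 6 comparisons, 0.002). No difference between SJL ages passed the test: it was -2.71 percentage points for 6 months minus 6 weeks (exact permutation p = 0.0571, adjusted 0.0686), 1.94 for 12 minus 6 months (exact permutation p = 0.0571, adjusted 0.0686) and -0.772 for 12 months minus 6 weeks (exact permutation p = 0.429, adjusted 0.429).

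**Figure D1:**
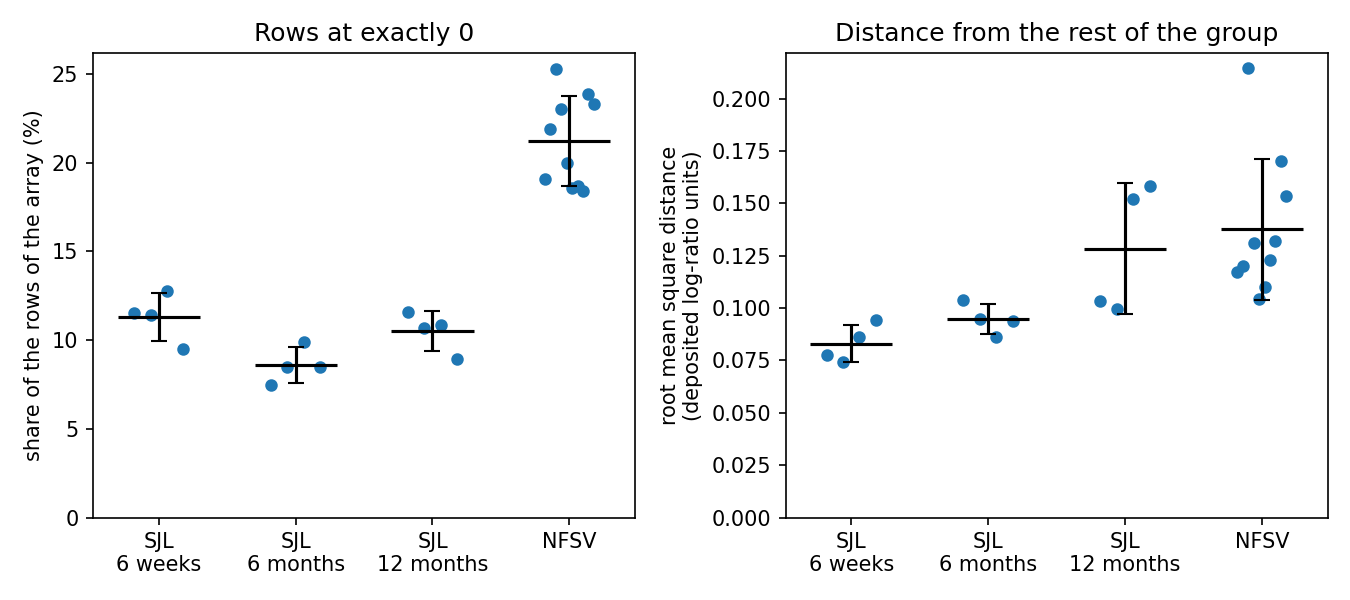
Share of rows at exactly 0 (left, %) and root mean square distance of each array from the mean of the other arrays of its group (right, deposited log-ratio units) for the 4 groups; points are arrays, lines are means and bars are SD. All 12 SJL arrays lie below the 10 NFSV arrays on the left, and SJL 12 month replicates 3 and 4 lie highest among the SJL arrays on the right.

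The comparison of SJL mice at 12 months with 6 weeks spans the whole age range sampled. Of 28371 probes, 1714 (6.04%) differed, 785 with a higher and 929 with a lower deposited ratio at 12 months (limma, adjusted p under 0.05). The balance depended on the scaling: 54.2% of these calls were lower, against 50.3% of 2262 calls after scale normalization, 46.1% of 2333 after quantile normalization and 49.5% of 3191 without SJL 12 month replicate 3, so no direction is given for the whole list. The 1714 differences had a median size of 0.275, which is 1.88-fold if the logs are base 10 and 1.21-fold if base 2. Among the 784 probes that moved by at least 0.301, a 2-fold change on a base 10 scale, 572 (73.0%) were lower at 12 months and 212 were higher. The share lower lay between 66.1% and 73.2% under the other scalings tried. The 2 groups fitted alone gave 1061 probes, and weighting the arrays by their precision gave 7951. Leaving out SJL 12 month replicate 3 raised the count to 3191, and leaving out SJL 6 week replicates 1, 3 or 4 lowered it to 1044, 892 or 1131.

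The largest falls were those of probes 28633 and 19186. Probe 28633 had a mean ratio of 0.81 ± 0.14 (SD, n = 4) at 6 weeks, -0.15 ± 0.47 (n = 4) at 6 months and -0.90 ± 0.28 (n = 4) at 12 months, and of 0.08 ± 0.26 (n = 10) in NFSV mice. It fell by 1.71 (SE 0.20, limma adjusted p = 0.00016) from 6 weeks to 12 months, 51.1-fold if base 10 and 3.27-fold if base 2. Probe 19186 went from 0.97 ± 0.21 (n = 4) to -0.46 ± 0.64 (n = 4), a difference of -1.44 (SE 0.31, limma adjusted p = 0.0092). Its mean in NFSV mice was 1.00 ± 0.32 (n = 10), and SJL mice at 6 weeks lay -0.02 from it (SE 0.26, limma adjusted p = 0.96). The largest rises were those of probes 17288 and 29842. Probe 17288 rose from -1.47 ± 0.14 (n = 4) to -0.45 ± 0.29 (n = 3), a difference of 1.02 (SE 0.17, limma adjusted p = 0.003). Probe 29842 rose from -1.38 ± 0.05 (n = 4) to -0.43 ± 0.36 (n = 4), a difference of 0.95 (SE 0.14, limma adjusted p = 0.0013). At 6 months all 4 probes had means between those at 6 weeks and 12 months, but none of the 4 passed the threshold against 6 weeks (limma adjusted p 0.12 to 0.75). SJL 6 month replicate 1 lay nearest to the 12 month means in all 4 probes. Without it the differences of 6 months from 6 weeks went from -0.96 to -0.74 for probe 28633, from -0.48 to -0.12 for 19186, from 0.38 to 0.23 for 17288 and from 0.40 to 0.28 for 29842. By the rule of choice, no 12 month array of these probes overlapped a 6 week array.

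**Figure D2:**
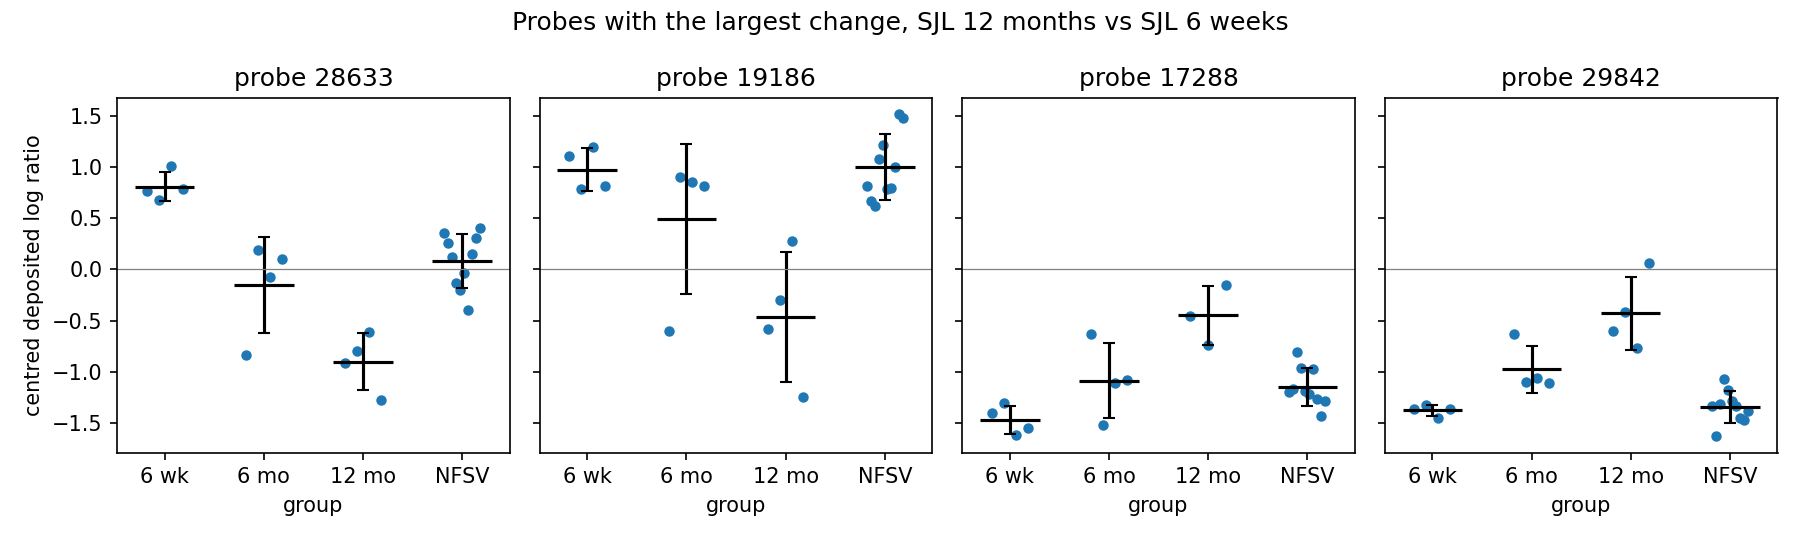
Centred deposited log ratio of the 2 probes that fell most (28633 and 19186) and the 2 that rose most (17288 and 29842) from 6 weeks to 12 months in SJL mice, with the NFSV mice beside them; points are arrays, lines are means and bars are SD. The means at 6 months lie between those at 6 weeks and 12 months for all 4 probes, as at 1653 of the 1714 called probes. Probe 28633 goes from 0.81 to -0.90.

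Far fewer probes passed the threshold over either part of this span. SJL mice at 6 months and 6 weeks differed at 6 probes, all 6 with a lower ratio at 6 months and 0 with a higher one, while 2191 probes had an unadjusted limma p under 0.05. The 2 groups fitted alone gave 28 probes, 89.3% of them lower, array weights 621, 66.5% lower, and keeping exact zeros 74, 62.2% lower. Leaving out any 1 of the 8 arrays compared gave 2 to 5 probes (5 without SJL 6 week replicate 3, and 2 or 3 without any other), and leaving out SJL 12 month replicate 3 or NFSV replicate 3 gave 10. Between 12 and 6 months 14 probes differed, 11 higher and 3 lower at 12 months, with 12 of them moving by at least 0.301. That count was 1 when only the 2 groups were fitted and 28 without SJL 12 month replicate 3. The majority turned without SJL 6 month replicate 1, with 63.8% of 58 calls lower, and with array weights, with 50.9% of 1685 lower, and 48.1% of 206 calls were lower with exact zeros kept, against 21.4% of the 14, so no direction is given for this list. It was 9, 7 and 5 without SJL 6 month replicates 2, 3 and 4, and 9 without SJL 12 month replicate 4. Another split of the same 8 arrays gave 565 probes.

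The size of the change could be estimated over all probes without a threshold. After subtraction of the error variance, the root mean square difference was 0.074 between 6 months and 6 weeks (0.065 to 0.079 with any 1 array of the 2 groups left out), 0.115 between 12 months and 6 weeks (0.108 to 0.131) and 0.062 between 12 and 6 months (0.049 to 0.080). With the variance pooled over the 4 groups, as first computed, these differences were 0.039, 0.106 and 0.050. By the estimate with group variances, 56.2% (44.8% to 63.9% with any 1 array left out) of the change from 6 weeks to 12 months was present at 6 months, and by the pooled one 45.8%. This share is the mean product of the 6 and 12 month differences from 6 weeks over the mean square 12 month difference. Error variance was subtracted from both, and the share is not a ratio of the sizes above.

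The differences of the 2 later ages from 6 weeks were compared across probes. Both are measured against the same 6 week arrays, which by itself produces a correlation. The differences at 6 and 12 months from 6 weeks correlated across probes at r = 0.663, against 0.384 in 20 simulated data sets with unchanged groups (0.502 when these used the pooled variance), and 74.9% of probes had the same sign against 61.1% in the simulations. The covariance was 0.00959 against a simulated 0.00232, a difference of 0.00727, or 0.00507 when the simulations used the pooled variance. With 2 of the 6 week arrays in each comparison, so that no array was shared, the covariance was 0.00687 to 0.00793 and r was 0.386 to 0.483 over 6 splits. Probes are not independent replicates, so no p-value is given. Of the 6 probes called at 6 months, 4 were also called at 12 months in the same direction, against 0.197 expected of independent lists. The lists are not independent, since both use the same 6 week arrays. At most 2 calls were shared in the simulations. But these held only 0.9 calls at 6 months and 9.25 at 12 months on average, against 6 and 1714 observed. Neither value is therefore a measure for the 4 shared calls. Without shared arrays the calls could not be compared, because 5 of the 6 splits called 0 probes at 6 months.

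The spread between the mice of a group was compared between ages. The distance of an array from the rest of its group was 0.083 ± 0.009 (SD, n = 4) at 6 weeks, 0.095 ± 0.007 (n = 4) at 6 months and 0.128 ± 0.031 (n = 4) at 12 months, and 0.138 ± 0.034 (n = 10) in NFSV mice. The mean distance was larger at 12 months than at 6 weeks (difference 0.045, exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow), but this did not pass adjustment over the 3 age comparisons (adjusted 0.0857). SJL 12 month replicates 3 and 4, at 0.152 and 0.158, lay farther out than replicates 1 and 2, at 0.103 and 0.0995. With values of exactly 0 kept, the difference was 0.033 (exact permutation p = 0.0857). Each distance was taken from the mean of the other arrays of its group, so the 4 distances of a group are not independent. Replicates 3 and 4 at 12 months also raise the distances of replicates 1 and 2. The highest correlation between 2 arrays was 0.9671 at 12 months, above the median of 0.9646 at 6 weeks. The p-values therefore do not show that the spread rose across all 12 month mice.

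The SJL mice of each age were also set against the NFSV mice, the normal control. SJL mice at 6 weeks differed from NFSV at 6917 of 28371 probes (24.4%), 4067 higher and 2850 lower in SJL. At 6 months 8699 probes (30.7%) differed, 4779 higher and 3920 lower. At 12 months 10553 probes (37.2%) differed, 5926 higher and 4627 lower. Without centring, the majority turned, and the share lower in SJL went from 41.2% to 56.5% at 6 weeks, from 45.1% to 56.7% at 6 months and from 43.9% to 56.2% at 12 months, so no overall direction is given. The median size of the called differences was 0.234 at 6 weeks, 0.213 at 6 months and 0.214 at 12 months.

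**Figure D3:**
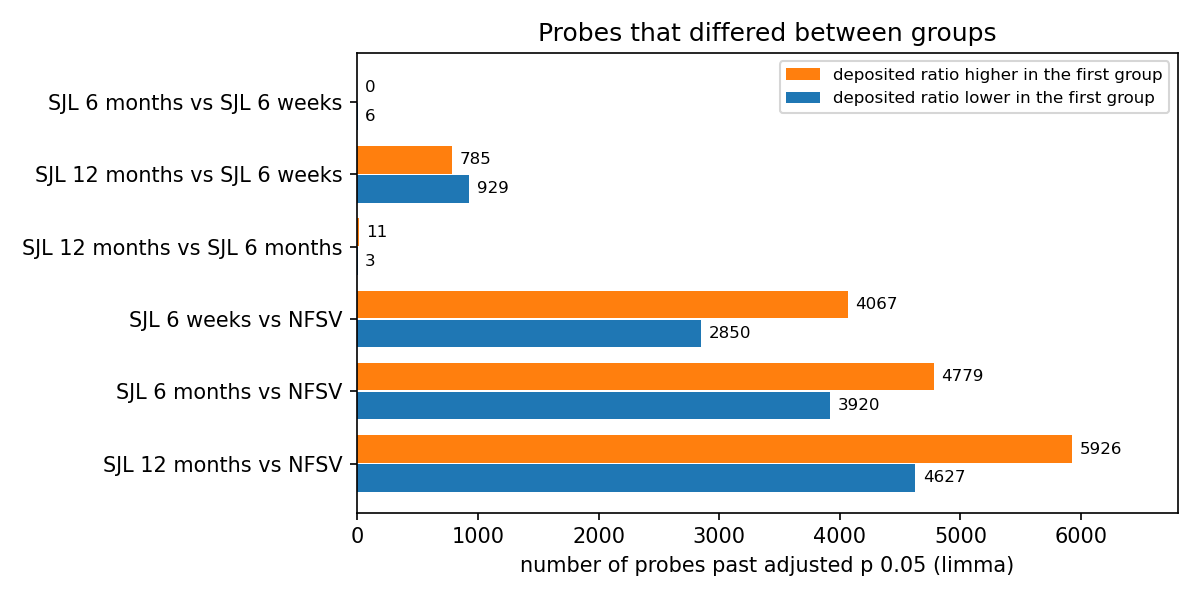
Number of probes past a limma adjusted p of 0.05 in each of the 6 comparisons, split by whether the deposited ratio was higher or lower in the group named first. The 3 comparisons with NFSV give 6917, 8699 and 10553 probes in all, against 1714 or fewer between SJL ages.

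Over all probes, the root mean square difference from NFSV after subtraction of the error variance was 0.176 in SJL mice at 6 weeks (0.173 to 0.181 with any 1 array left out), 0.184 at 6 months (0.182 to 0.188) and 0.192 at 12 months (0.185 to 0.207). Each exceeded the 0.115 between SJL mice at 12 months and 6 weeks. The mean correlation between arrays of the 2 strains was 0.874 with SJL mice at 6 weeks, 0.861 at 6 months and 0.833 at 12 months. These values are not corrected for the spread within groups. The median correlation between SJL arrays of the same age fell too, from 0.9646 at 6 weeks to 0.9564 at 6 months and 0.9115 at 12 months. The fall between strains therefore need not be a move away from NFSV. The age of the NFSV mice is not given, and their arrays had more rows at 0 than any SJL array, so strain, age and the measured arrays change together in these 3 comparisons. Of the 4 probes named above, probe 29842 differed from NFSV at 12 months by 0.91 (SE 0.12, limma adjusted p = 6.1e-06) and at 6 months by 0.37 (SE 0.12, adjusted p = 0.02), but at 6 weeks by -0.03 (SE 0.12, adjusted p = 0.88). Probe 28633 was above NFSV at 6 weeks by 0.73 (SE 0.17, limma adjusted p = 0.0031) and differed from it at 12 months by -0.98 (SE 0.17, adjusted p = 0.00013). The probes were chosen for their large change between 6 weeks and 12 months. Their comparisons with NFSV at these ages reuse the same SJL arrays and give no separate support.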

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

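The tests of missing values as the source of most calls, of label swaps, of array noise and detection on SJL 12 month replicate 4, of the separate batch and of the direction of the ratios were chosen after the results had been seen.

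A difference between SJL and NFSV spleens that changes with SJL age was found at 1714 probes for 12 months against 6 weeks, at 6 probes for 6 months against 6 weeks and at 14 probes for 12 against 6 months, the counts of the age comparisons themselves. Outside the tested probes, 313 probes had a value on all 4 SJL arrays at 6 weeks and were at exactly 0 on all 10 NFSV arrays. The same held for 649 probes at 6 months and for 383 at 12 months. No probe was at 0 on all SJL 6 week or all 6 month arrays with a value on all NFSV arrays, and 1 was for 12 months. The NFSV arrays had more rows at 0 in general (21.2% on average, against 8.59% to 11.3% in the SJL groups), which favours this imbalance. The counts therefore do not show probes expressed in SJL spleens alone.

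Of 31 sets of values tested for a lone extreme array, 4 had one, where chance gives about 1 in 20. In probes 19186 and 29842, SJL 6 month replicate 1 stood at -0.600 and -0.630, with the nearest of the other 6 month arrays at 0.815 and -1.06. NFSV replicate 3 had a mean correlation of 0.855 with the other NFSV arrays, where the next lowest was 0.907, and a median of 0.141 over the probes with a value on all arrays, where the next highest was 0.080.

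Probes differing between SJL and NFSV spleens were the first pattern weighed. Other splits of the arrays gave fewer calls in each comparison, which argues against chance. At 6 weeks 1 of 100 splits reached 6917 probes (highest other 121), and at 6 months 1 of 100 reached 8699 (highest other 845). At 12 months 1 of 100 reached 10553 (highest other 6400, a split that kept 3 of the 4 SJL mice together). A share of 0.933 of the 12 month calls lay at the 25557 probes with a value on all arrays, where no value was missing. But the filter fixed this in advance, since 25557 of the 28371 tested probes were of this kind. The share therefore does not weigh missing values or poorer detection on the NFSV arrays as a cause. The share called was 1.52 times as high at these probes (38.5%) as at the other tested probes (25.3%). This decides nothing about fewer detected probes, since the others were tested on fewer arrays. A trend of the ratios with their level is argued against, since a share of 0.888 of the 12 month calls passed again once each array's trend was removed. A separate batch for the strains cannot be told apart from the strain, because the lowest NFSV share of rows at 0 lay 5.68 percentage points above the highest SJL share and no array of one strain lies on the other side, and the unstated NFSV age stays open and untested too.

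The second pattern was that of arrays that depart from their group at 6 and 12 months, where the comparison of 12 with 6 months called 14 probes, and 4 of 35 splits of the 8 arrays called as many, so chance is not excluded there. The highest, 565 probes, set SJL 6 month replicate 1 with SJL 12 month replicates 1, 2 and 4 against the rest, which points to a structure of the samples. That is the grouping a swap of the labels of SJL 6 month replicate 1 and SJL 12 month replicate 3 would give. Replicate 3 lay 0.044 farther from SJL 6 month replicates 2 to 4 than the farthest of those lay from its own group. But it lay far from the other 12 month arrays too, so this distance cannot decide on its label. SJL 6 month replicate 1 lay inside the 12 month range (-0.049 by the same measure). Both arrays lay nearer to the other age than to their own, SJL 12 month replicate 3 at 0.142 against 0.152 and SJL 6 month replicate 1 at 0.099 against 0.104. A swap therefore stays open. So do a wrong label of a single array and a different stage of disease, which are untested. For SJL 12 month replicate 4, fewer detected probes are excluded (-3.82 percentage points against the highest other SJL array), while array noise stays undecided: its deviation had r = 0.00696 with the change from 6 weeks to 6 months (-0.054 to 0.065 with any 1 array left out), and r from -0.282 to 0.276 with the deviations of single arrays outside its group, where SJL 12 month replicate 3 had -0.232 to 0.219, so neither value decides, and a different course of disease in that mouse is untested.

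Large values on probes that are at 0 on most arrays were the third pattern. Of 3150 probes at exactly 0 on at least 8 of the 12 SJL arrays, 426 had values over 0.5 in size, and 411 of these 479 values were negative, a share of 0.858 (66.7% to 98.1% on single arrays). The share was 0.480 on probes with a value on all arrays, which argues against a general excess of negative values. A candidate explanation is that the ratio is reference over spleen, so that a lower value means more spleen RNA. It rests on exact zeros meaning that neither channel stood above background, which is not stated. The signs were less one-sided, at any size, on probes at 0 on all NFSV arrays with a value on all SJL arrays of an age. There 199 of 313 had a negative mean at 6 weeks, 377 of 649 at 6 months and 226 of 383 at 12 months.

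For the 2 comparisons with 6 week SJL mice, 1 of 35 splits reached 1714 probes at 12 months (highest other 1) and 1 of 35 reached 6 probes at 6 months (highest other 1). This is the smallest share that 35 splits can give, and it was not adjusted over the 3 age comparisons. Taken singly it argues against chance for each comparison, but a share at its floor cannot exclude chance. The 6 calls also rest on few probes: they were 2 to 5 without any 1 of the 8 arrays. Up to 3 were called in 20 simulated data sets without effects.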

How the results depend on the processing

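The averaging of probes per gene and the gene list alternatives were not run because rows carry no gene name. Keeping exact zeros, removing each array's trend, leaving out the pair of outlying arrays, the 2-fold limit on base 2, the size estimates with their pooled variance and all alternatives on distances were chosen after seeing the data. Of 242 alternative values of counts, overlaps, distances and sizes, 184 were kept. They stayed within 1.5 times, on their side of the threshold or, for sizes, in the range over left-out arrays. For each comparison, 22 of the counts came from leaving out 1 array, often an array of neither group compared. Such an array acts only through the shared variance. The share kept therefore overstates how little the counts depend on single arrays. All 139 alternative values of the 4 named probes kept direction and threshold, with limma adjusted p up to 0.036. These probes were chosen for their large changes on the same arrays, so this gives no further support. For 12 months against 6 weeks, 12 against 6 months and 6 months against 6 weeks, in that order, leaving out 1 array gave 892 to 3191, 5 to 58 and 2 to 10 probes, array weights 7951, 1685 and 621, the 2 groups alone 1061, 1 and 28, the base 10 limit of 2-fold 784, 12 and 3, the base 2 limit 10, 0 and 0, and an adjusted p under 0.01 gave 543, 3 and 2. For SJL at 6 weeks, 6 months and 12 months against NFSV, the base 10 limit gave 2473, 2604 and 3094, the base 2 limit 55, 69 and 85, and an adjusted p under 0.01 gave 3809, 4944 and 6671. Array weights gave 12428, 11800 and 13666, which do not rise steadily with age, and the 2 groups alone gave 6878, 7921 and 8249. The 12 against 6 month count was 33 after quantile normalization, 27 after scale normalization, 24 with trends removed and 206 with zeros kept. The 6 month against 6 week count was 74 with zeros kept and 17 without SJL 12 month replicate 4 and NFSV replicate 3. Without centring, 35% of 20 calls between 12 and 6 months were lower, against 21.4% of 14, and 88.9% of 9 calls between 6 months and 6 weeks, against 100% of 6. Calls shared by 6 and 12 months went from 4 to 7 without centring and were at most 1 with 2 of the 6 week arrays in each comparison, which says nothing of the overlap because 5 of the 6 splits called 0 probes at 6 months. The distance of 12 month arrays exceeded that of 6 week arrays by 0.0326 with zeros kept (exact permutation p = 0.0857; 0.0286 to 0.0857 over its alternatives). With the variance pooled over the 4 groups, as first computed, the root mean square difference was 0.039 between 6 months and 6 weeks, 0.106 between 12 months and 6 weeks, and 0.171 and 0.181 between NFSV and SJL mice at 6 weeks and 6 months. With the replicate number as a block (replicate block), the 6 month against 6 week count was 19 and the 12 against 6 month count 4, and the other 4 counts stayed within 1.5 times. The number was not taken to pair the mice, because 6 of 12 same-numbered SJL pairs, not all, had deviations that correlated over 0.1 (-0.0136 to 0.207). This does not exclude a pairing. The mean r of the 12 same-numbered pairs was 0.0907, a hint from the data and not from the design. The -0.0295 of pairs with different numbers adds nothing, since the deviations cancel within a group. Of the 12 SJL arrays, 3 correlated best with their own number at both other ages. Stricter thresholds lower the counts by construction. For the other changes, those from leaving out arrays included, the cause was not tested. Signal over background was not used here, so what dim spots limit is unknown.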

Other observations

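Within the SJL ages, some probes were at exactly 0 on every array of one age and had a value on every array of another. There were 33 such probes with a value at 12 months and 0 at 6 weeks, 25 of them with a negative mean, and 16 with a value at 6 weeks and 0 at 12 months, 15 of them negative. Between 6 months and 6 weeks 53 probes had a value at 6 months alone, 33 of them negative, and 2 at 6 weeks alone, 1 of them negative. Between 12 and 6 months 63 probes had a value at 6 months alone, 45 of them negative, and 8 at 12 months alone, 5 of them negative.

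When SJL 12 month replicate 4 was left out, 1006 of the 1714 probes called between 12 months and 6 weeks were called again, among 1178 calls.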
